A study of Mus musculus with 4 samples.

How the data were processed

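Small RNA libraries from 4 NIH-3T3 samples (2 control, 2 given 500 nM thapsigargin for 24 h) were made with a small RNA kit that ligates adapters to both ends, per the labels' protocols. Base calling with CASAVA 1.8.1, adapter removal with cutadapt, alignment with Bowtie and testing with DESeq 1.4.1 are named in the submitters' processing notes, which also name a mouse build other than the GRCm38 reference held here. No coordinates are therefore given, and RefSeq genes of GRCm38.p6 served only for which miRNA genes neighbour each other. The notes name DESeq, while the columns of the authors' deposited table are those of an early edgeR test. Which produced it is not given in the sources used here.

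The authors deposited, per sample, whole-number counts of each distinct read and of each miRNA, split into mature, star, predicted star and hairpin tables. Each table was given once for reads matching 1 miRNA and once for ambiguous reads. The deposited tables also give each value as a percent of all reads entering the count. The authors' comparison table holds log2 fold changes and p-values, per the file headers. Read-table counts were summed here to 630 arms by library, with 1 library size over mature and star arms. Ambiguous and hairpin reads were left out. For 3 libraries the deposited mature summary matched the read table, apart from 1 of 364 names in control replicate 1. For thapsigargin replicate 2 only 15 of 395 names matched, so that summary was not used and the counts of all libraries came from the read tables.

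Differences were tested with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood test was two-sided, with TMM scaling, trended dispersion, robust fitting and filterByExpr (minimum count 10), which kept 310 arms. The untested arms held 2744 reads. The p-values were adjusted by the Benjamini-Hochberg method at 0.05. Scaling factors were 1.40 and 0.900 in the controls and 1.11 and 0.712 with thapsigargin, and the biological coefficient of variation was 0.447. The standard error was taken from the fold change and its F statistic. Of 20 miRNA lists, 15 had at least 3 tested arms and were tested with camera in limma 3.58.1 (preset correlation 0.01), with an estimated correlation and fry beside it. Lists, tests and the rule for named miRNAs were fixed before the data were examined. Arm ratios were tested with edgeR's diffSpliceDGE, and class shares and read lengths with exact permutation tests in scipy 1.17.1. Ratios of low counts have exact binomial 95% intervals, and a group at 0 was set to a floor of 3 counts.

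The rule named all tested arms of the miR-322 and miR-503 cluster, up to 4 members per list by smallest p, the 5 most abundant arms, up to 5 hairpins of the arm ratio test, and called arms with a mean count of at least 50. As no arm was called, the 5 with the smallest p in each direction took the place of the called arms, as values only. miR-217, miR-217* and miR-671-5p were named after their values were seen.

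On simulated counts with the observed spread, 7.5%, 38% and 94.5% of arms changed 2-fold, 4-fold and 16-fold were called, and 0.48% of unchanged arms. With a low spread the shares were 83%, 97.5% and 100%. The list test called the let-7 family, moved by 1 on the log2 scale, in 20 of 20 runs, and 0 of 280 tests of unmoved lists. Arms were drawn independently in these runs, so they do not show how often lists of correlated arms are called falsely. The arm ratio test was simulated at a fixed spread lower than the observed spread. There it called 86 of 100 star arms moved by 4 on the log2 scale and 9 of 710 others. Its power at the observed spread was not simulated, nor were smaller moves.

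Alternatives were other scalings, filters and tools (DESeq2 1.42.0, limma-voom), ambiguous reads as features, the mature table alone, the most abundant arm left out, the replicate number as a block and each library left out. After seeing the data, 4 more were added for the abundance test. These were control replicate 1 reads with the first base taken off and those then under 18 nt dropped, the same with the block, the unmatched summary table, and an edgeR exact test without a filter. The first step dropped 56287 reads (1.42%), and 99.8% of the remaining reads were found in the other libraries. Reads found there took the assignment they had there, which moved 29689 reads (0.762%) to another arm or read class. Class shares were not recomputed on the shortened reads, since their assignment came from the other libraries.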

Results

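Small RNA was sequenced from NIH-3T3 cells, an established mouse embryonic fibroblast line, with and without thapsigargin. Thapsigargin blocks the SERCA pump, which fills the endoplasmic reticulum (ER) with calcium, so the drug empties the ER calcium store and brings on ER stress. The control group and the group given 500 nM thapsigargin for 24 h each held 2 libraries. The labels do not say whether the replicates were separate cultures. A p-value that compares the libraries of the groups therefore measures only the spread between these samples, which may be technical. Camera with a preset correlation, and permutations over arms or hairpins, compare arms with other arms instead. The reads entering the miRNA count numbered 4206707 and 3848203 in control replicates 1 and 2, and 6023406 and 2883126 in thapsigargin replicates 1 and 2. Of these, 3857002, 3633414, 5570971 and 2685965 were assigned to 1 miRNA arm. miR-10b alone took 35.7%, 56.6%, 41.7% and 53.3% of the arm reads. Intervals and lower bounds on counts cover counting error only.

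The comparison asked which miRNAs differ after ER calcium depletion. No arm passed the test. The star arm of miR-216a had 2 and 1 reads in the control libraries and 31 and 26 in the thapsigargin libraries, a ratio of 20.3 with a counting interval of 6.62 to 102. Its neighbour on chromosome 11, miR-216b, had 2 and 1 against 18 and 8 reads, a ratio of 9.28 (counting interval 2.84 to 47.9). A further gene beside them, miR-217, had 0 reads in both controls and 12 and 10 with thapsigargin, at least 7.85-fold higher against a floor of 3 counts over the group, a bound that leaves out the counting error of the thapsigargin reads (the exact 95% counting interval of the ratio starts at 5.87). miR-217* had 0 and 0 against 16 and 3 reads, at least 6.78-fold higher by the same floor (counting interval from 5.0). Reads of the 6 arms of these hairpins summed to 7 in the controls and 135 with thapsigargin. Among them, miR-216a had 1 and 0 control reads against 2 and 3, a ratio of 5.36. Its counting interval of 0.60 to 253 includes no change. miR-216b* had 0 and 0 against 6 and 0 reads.

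Next by p on the higher side, miR-708* stood at 64.3 ± 2.66 CPM (SD, n = 2) in controls and 224 ± 137 CPM with thapsigargin, a log2 fold change of 1.8 (SE 0.60). miR-92a-1* had 7 and 6 control reads against 27 and 22, a log2 fold change of 2.29 (SE 0.78), and miR-101b had a log2 fold change of 1.52 (SE 0.54). With the first base taken off the reads of control replicate 1 and the shortened reads assigned as in the other libraries, its miR-101b count went from 831 to 1925. The miR-101b difference thus depends in part on read handling. On the lower side, miR-503 had 19 and 10 control reads against 4 and 0, a log2 fold change of -2.79 (SE 0.85). miR-450b-5p stood at 67.5 ± 7.44 CPM (SD, n = 2) in controls and 26.7 ± 5.82 CPM with thapsigargin, a log2 fold change of -1.34 (SE 0.51). The related miR-99a, miR-99b and miR-100, which share a seed, had log2 fold changes of -1.32 (SE 0.52), -1.41 (SE 0.57) and -1.24 (SE 0.52). With each library left out in turn, the log2 fold change ranged from 1.0 to 2.27 for miR-708*, 1.5 to 2.83 for miR-92a-1*, 1.07 to 2.14 for miR-101b, -1.94 to -0.68 for miR-99b, -1.70 to -1.02 for miR-99a and -1.72 to -0.79 for miR-100. For miR-503 the range was -6.56 to -2.29, and its lower end is set against 0 reads, so it depends on the prior count and is no bound.

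edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 310 arms at an adjusted p of 0.05, and the smallest adjusted p was 0.260, for miR-216a*. Without a replicate block, 12 arms had an unadjusted p under 0.05 in this test, 7 higher and 5 lower, where chance alone gives 15.5. DESeq2 and limma-voom also called 0 arms, with 15 and 12 at an unadjusted p of 0.05. In 104 arms (33.5%) the libraries of the groups did not overlap, and chance gives 33.3%. With the observed spread, simulated 2-fold, 4-fold and 16-fold changes were called in 7.5%, 38% and 94.5% of arms, so smaller differences were mostly not detectable here. Without control replicate 1 the count was 1 arm (the predicted star of let-7d), and without control replicate 2 it was 3 (miR-671-5p and the predicted stars of miR-196a-1 and miR-503). All 3 rest on reads of control replicate 1, at 81, 21 and 24 reads there as deposited and 10, 2 and 3 with its reads made like the others. Without the filter on low counts it was 3 of 630 arms, with miR-216a* and miR-217 higher and miR-671-5p lower.

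**Figure D1:**
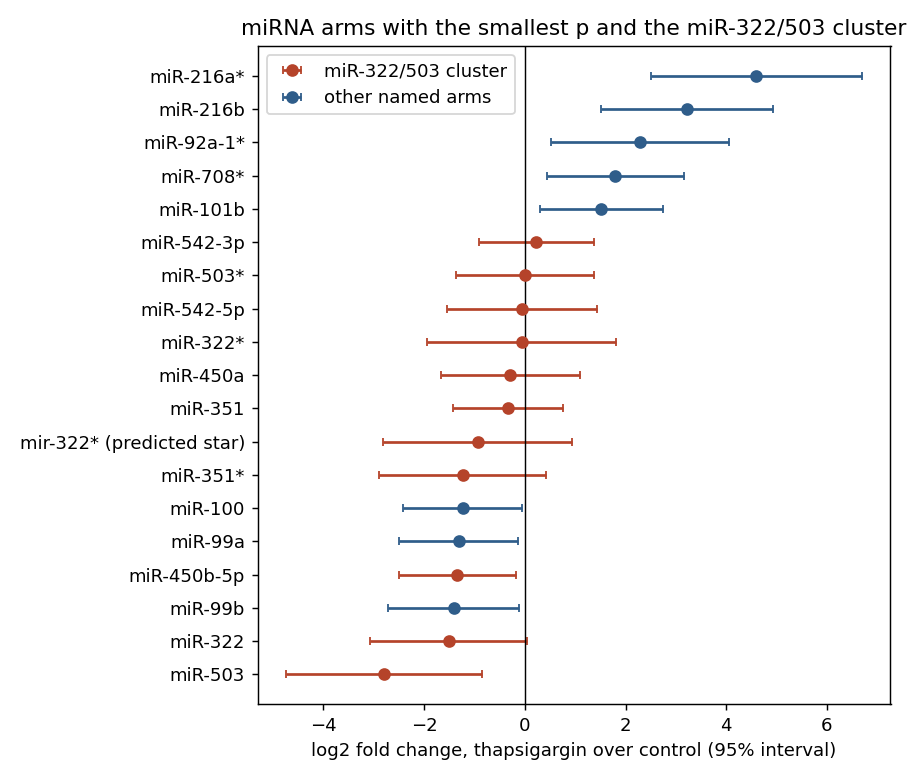
Log2 fold change of thapsigargin over control (x axis) for miRNA arms (y axis), from 2 libraries per group. Shown are the 5 arms with the smallest p in each direction and the tested arms of the miR-322 and miR-503 cluster. Points mark the estimate and bars its 95% interval. miR-216a* lies highest at 4.59 and miR-503 lowest at -2.79, and no arm passed the adjusted test.

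The miR-322 and miR-503 cluster is a group of neighbouring miRNA genes on chromosome X that includes miR-322, miR-503, miR-351, miR-542 and miR-450. It had the lowest mean log2 fold change of the 15 tested lists, though not the lowest median. Of its 11 tested arms, 9 had log2 fold changes below 0, with a median of -0.34 and a mean of -0.76. Several of these arms share a hairpin, so they are not independent. miR-503* also lay below 0 under the other scalings, as did miR-542-3p when scaled by total reads. Summed over the list, the arms stood at 8714 and 4585 CPM in the controls and 5100 and 5098 CPM with thapsigargin, so the groups overlapped. The median log2 fold change of the tested arms was -0.0072 with TMM scaling and -0.36 when scaled by total reads alone, so counts of arms above or below 0 hold for TMM scaling. miR-322, whose published target in ER calcium depletion is a protein disulfide isomerase, stood at 430 ± 344 CPM (SD, n = 2) in controls and 150 ± 36.7 CPM with thapsigargin, a log2 fold change of -1.52 (SE 0.67) that ranged from -2.18 to -0.30 with each library left out in turn. miR-351 had a log2 fold change of -0.34 (SE 0.48), miR-542-3p of 0.23 (SE 0.50) and miR-503* of 0.01 (SE 0.60). The list fell by the camera test with a preset correlation (adjusted p = 0.0235 over 15 lists), but not with an estimated correlation (adjusted p = 0.900), and fry gave an adjusted p of 0.757. The call also ended without control replicate 1 (mean log2 fold change -0.09, adjusted p = 0.946) and without thapsigargin replicate 2 (mean -0.93, adjusted p = 0.350). No member passed the test over all arms, and 0 passed when adjusted over the list alone. The list was chosen with these cells' published results in mind, so it is not independent evidence of its direction. miR-322 had 3644 and 611 reads in the control replicates and 1092 and 238 with thapsigargin, and 45.4% of its reads in control replicate 1 were 18 nt long, against 1.26% at most in the other libraries. Its commonest reads in control replicate 1 were CAGCAGCAATTCATGTTTTGGA (1776 reads) and CAGCAGCAATTCATGTTT (1624 reads), while in control replicate 2 the commonest was AGCAGCAATTCATGTTTTGGA (541 reads), without the first base. With the reads of that library made like the others, its log2 fold change was -0.88 (SE 0.53).

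miRNAs reported elsewhere as raised by ER stress had 8 of 14 tested arms above 0, with a median log2 fold change of 0.39 and a mean of 0.54. That mean ranged from 0.20 to 0.72 with each library left out in turn. miR-216b belongs to this list, as do miR-708*, miR-101a at 0.92 (SE 0.51) and miR-30c-2* at 0.89 (SE 0.51). The miR-101a value depends in part on read handling. Its count in control replicate 1 was 2547 as deposited and 5185 with the reads of that library made like the others. The list was not called by camera (adjusted p = 0.0858; 0.900 with an estimated correlation), and fry, which asks whether members move on balance 1 way, gave an adjusted p of 0.0470. No member passed over all arms, and 1 did when adjusted over the list alone, where the smallest adjusted p in edgeR's test was 0.0317. miRNAs reported as lowered by ER stress had 20 of 36 arms below 0 (median -0.05, camera adjusted p = 0.847).

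The let-7 family, repressors of growth genes, had 9 of 17 arms above 0 (median 0.07, camera adjusted p = 0.598). let-7f stood at 10512 ± 3790 CPM (SD, n = 2) in controls and 25796 ± 7393 CPM with thapsigargin, and let-7i had a log2 fold change of 1.16 (SE 0.52). The growth-promoting clusters of the miR-17-92 family had 10 of 15 arms above 0 (median 0.11, camera adjusted p = 0.534), with miR-92a at 0.56 (SE 0.44) and miR-25 at 0.90 (SE 0.50). Fibroblast and mesenchymal miRNAs had 13 of 27 arms above 0 (median -0.10, camera adjusted p = 0.847). Within this list miR-143, an abundant smooth-muscle and fibroblast miRNA, stood at 82938 ± 11516 CPM (SD, n = 2) in controls and 148727 ± 1969 CPM with thapsigargin. The Sfmbt2 cluster had 5 of 6 arms below 0 (camera adjusted p = 0.534). Its mean log2 fold change ranged from -1.25 to -0.036 with each library left out, and it passed without control replicate 1 (9 arms, mean -1.11, camera adjusted p = 0.0305). The Dlk1-Dio3 cluster had 3 of 3 arms below 0 (camera adjusted p = 0.668). Camera adjusted p was 0.847 for the lists linked to p53, the miR-29 family, the miR-30 family, the miR-23/27/24 clusters and hypoxia and metal stress, and 0.668 for mirtrons. In the p53-linked list the median lay above 0 and the mean below it, at -0.07. Each of these lists had 0 members past the threshold, over all arms and adjusted over the list alone.

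Embryonic stem cell markers had 0, 7, 4 and 2 reads in control replicates 1 and 2 and thapsigargin replicates 1 and 2. Epithelial markers had 11, 4, 19 and 7 reads, muscle markers 2, 0, 2 and 0, and the liver marker 0, 0, 1 and 1. Blood cell markers, mainly miR-155, had 441, 362, 620 and 184 reads. miRNAs also used as neural markers had 2743, 1020, 4469 and 1439 reads and 6 of 8 arms above 0 (median 0.36, camera adjusted p = 0.606). Their mean log2 fold change ranged from -0.60 to 0.57 with each library left out, and was below 0 without thapsigargin replicate 2. Of them, miR-9 stood at 352 ± 144 CPM (SD, n = 2) in controls and 663 ± 8.05 CPM with thapsigargin.

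The share of a hairpin's reads that came from its second arm was compared in 81 hairpins, and 0 passed the arm-level test in edgeR, with 3 at an unadjusted p of 0.05. For miR-143 the star arm gave 0.0177 ± 0.00998% of reads (SD, n = 2) in controls and 0.00369 ± 0.00119% with thapsigargin. For miR-101a the values were 0.406 ± 0.144% and 0.0768 ± 0.0359%, and for miR-99b 0.708 ± 0.338% and 2.99 ± 2.75%. miR-99a* took 2.53 ± 1.64% and 6.35 ± 0.625%, and miR-361* 3.61 ± 2.57% and 8.93 ± 1.19%. With each library left out in turn, the log2 ratio ranged from -2.78 to -1.56 for miR-143, -2.86 to -1.84 for miR-101a, 0.78 to 3.07 for miR-99b, 0.81 to 2.27 for miR-99a and 0.81 to 2.45 for miR-361. The smallest adjusted p was 0.273, for miR-143*, at a log2 ratio of -2.36. miR-143* had 122 and 26 reads in the controls and 26 and 13 with thapsigargin. With the reads of control replicate 1 made like the others it had 45 there, and the log2 ratio was -1.44 (adjusted p = 0.780 in edgeR). Without control replicate 2, 1 hairpin passed, miR-671.

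Reads assigned to 1 mature miRNA made up 96.1 ± 1.66% (SD, n = 2) of control and 97.2 ± 1.5% of thapsigargin table reads (exact two-sided permutation p = 0.667). Star reads made up 2.23 ± 0.666% and 1.61 ± 0.967% (exact p = 0.667), and ambiguous mature reads 1.25 ± 0.466% and 1.11 ± 0.508% (exact p = 0.667). Hairpin reads made up 0.803% in control replicate 1 and 0.0571% in control replicate 2, against 0.0961% and 0.0667% with thapsigargin (exact p = 1). With 2 libraries against 2, the smallest p this test allows is 0.333.

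Read length set control replicate 1 apart from the other 3 libraries, its own replicate included. Mean mature read length was 21.8 nt there, against 20.9 nt in control replicate 2 and 20.8 and 20.9 nt with thapsigargin (exact two-sided permutation p = 0.333). In 104 of 109 arms with at least 100 reads in each library, the mean was longest in control replicate 1. Over those arms the median difference between the control replicates was 0.971 nt. Among the 100 most abundant arms, the commonest first base lay 1 nt later in 98, 100 and 99 arms in the other 3 libraries. The commonest reads of those arms thus lacked the first base seen in control replicate 1. Which form is the full mature miRNA was not tested. Making the reads of control replicate 1 like the others takes a base off that library and restores none in the other 3. Reads shorter than the arm's commonest length made up 8.10 ± 5.79% (SD, n = 2) in controls and 14.5 ± 1.97% with thapsigargin (exact p = 0.333). Longer reads made up 47.9 ± 50.4% and 14.6 ± 0.774% (exact p = 1).

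**Figure D2:**
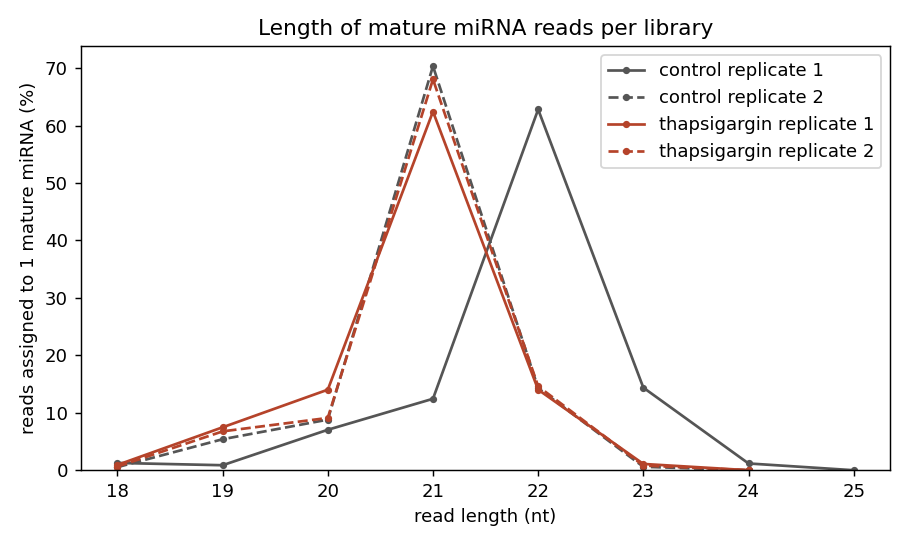
Share of reads assigned to 1 mature miRNA (y axis, percent) at each read length (x axis, nt), with 1 line per library. Control replicate 1 has its mean at 21.8 nt, and the other 3 libraries lie between 20.8 and 20.9 nt.

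In the authors' deposited table of the comparison, 2 of 324 miRNAs had an adjusted p under 0.05. These were miR-671-5p, with a log2 fold change of -3.76 and an adjusted p of 0.00642 in the authors' deposited table, and miR-217, with an adjusted p of 0.0140 there. Neither was among the 310 arms tested by edgeR's quasi-likelihood fit. Of the 217 arms in both, 199 had the same direction in the authors' deposited table, and the log2 fold changes correlated at 0.999. Over 321 miRNAs, the authors' values correlated at 0.868 with fold changes from the read tables. With the unmatched summary in place for thapsigargin replicate 2 the correlation was 0.174, which argues against its use in the authors' comparison. miR-671-5p had 81 and 6 reads in the controls and 6 and 0 with thapsigargin, so most of its reads came from control replicate 1, the library with the longer reads. With the reads of that library made like the others, an edgeR exact test gave miR-671-5p a log2 fold change of -1.41 and an adjusted p of 1, against -3.67 and 0.0105 as deposited. miR-217 had an adjusted p of 0.0199, against 0.0239 as deposited. The exact test with harmonised reads called 2 arms, miR-217 and miR-1937a (log2 fold change 3.90, adjusted p = 6.01e-05, against 1.91 and 0.491 as deposited). Harmonising left miR-1937a with 32 of its 399 reads in control replicate 1.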

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

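The tests on the summary table, the miR-322 difference and the miR-216 and miR-217 group were chosen after the results were seen, except the scaling alternative, which was planned.

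The deposited mature summary of thapsigargin replicate 2, which the comparisons do not use, held a strong signal absent from the controls. It gave 53501 reads to miR-295, a miRNA typical of embryonic stem cells, against 0 and 2 in the control read tables, and 92357 reads (25.2% of its total) to the embryonic stem cell list. The sample's own read tables held 2 reads of that list, which argues against another cell type in the sample. In 85 miRNAs the summary had over 10 times the reads of the read table, ambiguous reads included, which argues against another count of the same reads. Its percents imply a total of 470210 reads against 2883126 in the sample's other tables, consistent with a table made from another library. No effect of thapsigargin was tested as an explanation.

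miR-322 was lower with thapsigargin, but the controls differed from each other, at 673 and 187 CPM against 176 and 124 CPM. Making the reads of control replicate 1 like the others shrank the fold 1.55 times, consistent with read handling having enlarged it. Arms with the bases TGG after base 18, miR-322 among them, had a median of 27.6% 18-nt reads in that library. The 124 other arms had a median of 0.143% (permutation p = 4e-05, 7 TGG arms). Bases resembling the start of the 3' adapter may therefore have been trimmed there and such reads lost below 18 nt elsewhere. TGG does not cover every case, since miR-21, with TTG at those bases, had 35.1% 18-nt reads in that library. Whether read handling is the whole difference cannot be told apart from an effect of thapsigargin: the remaining log2 fold change of -0.88 (SE 0.53) lies between 1 and 2 SE from 0. The effect of the drug stays open.

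The arms of miR-216a, miR-216b and miR-217 were higher with thapsigargin, with 7 reads in the controls and 135 in the treated libraries. Harmonising left miR-216a* at 2 reads in control replicate 1, with a log2 fold change of 4.61, so it hardly tests the longer reads of that library. Control replicate 2, with read starts like those of the thapsigargin libraries, held 2 reads of the group against 85 and 50 there. This argues against the longer reads as the cause. Without composition scaling the log2 fold change of miR-216a* was 4.13. The scaling factors of the libraries were too close to each other to make or remove a difference of that size. This check could therefore not have implicated scaling, and it adds nothing to what the factors show. RNA of pancreatic cells, where this group is abundant, may also contribute. miR-148a was higher by 1.32 CPM and miR-375 by 0.628, against 3.58 for miR-217. They had 18 and 3 control reads against 25 and 6. The counting intervals of their ratios, 0.78 to 2.89 and 0.46 to 13.2, include no change. The rise predicted for this cause, at least that of miR-217, was not seen, nor was a fall. With no measured profile of such cells, this cause cannot be told apart from induction by thapsigargin, which stays open.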

How the results depend on the processing

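The alternatives with harmonised reads, the unmatched summary table and the edgeR exact test were chosen after the data were seen. Where no reason is given, the cause was not tested. The count of called arms was 0 with the other scalings, DESeq2, limma-voom, the stricter filter, ambiguous reads as features, the mature table alone, the most abundant arm left out, harmonised reads and an adjusted p under 0.10. It was 3 without a filter, 2 with the edgeR exact test and 0 to 3 with each library left out, where the lone sample of a group is assumed to vary like the others. Same-numbered samples deviated together (correlation 0.569), but 2 pairs that share only a number do not establish pairing. Control replicate 1 correlated more closely with thapsigargin replicate 1 (0.986) than with control replicate 2 (0.966). Control replicate 2 stood at 0.963 with thapsigargin replicate 2. The replicate block gave 0 called arms, and 6 together with harmonised reads. These were miR-216a* (edgeR adjusted p = 3.03e-06), miR-708* (0.0180), miR-92a-1* (0.0240), miR-1957 (0.0180) and miR-1937a (2.82e-10) on the higher side and miR-450b-5p (0.0337) on the lower. Neither change alone called an arm in this test. Arms at an unadjusted p of 0.05 numbered 30 with the block, 16 with harmonised reads and 51 with both, against 12 in the main test. Harmonising took the control replicate 1 reads of miR-1937a from 399 to 32. The miR-322 and miR-503 list was the 1 list called, and 0 were called with an estimated correlation. With fry the 1 list called was that reported as raised by ER stress. With each library left out 0 to 1 list was called, which was the Sfmbt2 cluster without control replicate 1 and the miR-322 and miR-503 list without control replicate 2 or thapsigargin replicate 1. Hairpins called in the arm ratio test were 0 to 1 with each library left out. Depth limits scarce arms, among them the miR-216 and miR-217 group and miR-503, at 31 reads or fewer per arm and library.

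Signs that turned belong to uncalled arms, given as log2 fold changes. The unmatched summary table, which appears to be of another library, turned 25 of 67 named arms: let-7f -0.034, let-7i -0.41, miR-101a -0.056, miR-10b -1.24, miR-127 8.04, miR-138 0.46, miR-143 -0.16, miR-155 -0.53, miR-181a -0.64, miR-1839-5p -0.17, miR-194 0.53, miR-210 -0.42, miR-22 -1.03, miR-24 -0.48, miR-29a -0.52, miR-29b -0.84, miR-322* 0.21, miR-410 7.28, miR-411 4.91, miR-467c 1.63, miR-467d 1.2, miR-467e 0.66, miR-467f 2.67, miR-542-3p -0.26 and miR-98 -0.21. Scaling by total reads gave a median over arms of -0.36, against -0.0072, and the turned arms lay above that median: miR-155 -0.26, miR-210 -0.18, miR-22 -0.084, miR-29a -0.096, miR-29b -0.14, miR-455* -0.21, miR-503* -0.25 and miR-542-3p -0.11. DESeq2 turned miR-155 -0.0045 and miR-503* -0.033, RLE factors miR-155 -0.0049 and miR-503* -0.027, upper quartile scaling miR-155 -0.044 and miR-503* -0.049, ambiguous reads miR-155 -0.013 and miR-503* -0.029, limma-voom miR-503* -0.012, the replicate block miR-503* -0.017, harmonised reads miR-503* -0.27 and harmonised reads with the block miR-503* -0.31. With harmonised reads the mean of the p53-linked list was 0.095, and the thapsigargin minus control difference was -0.0772 percentage points for shorter reads and 2.81 for longer reads, as the first base of control replicate 1 was then gone.

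With each library left out, arms whose sign turned ranged as follows: miR-10b -0.21 to 1.1, miR-155 -0.17 to 0.23, miR-322* -1.28 to 1.17, miR-351 -0.73 to 0.15, miR-410 -1.83 to 0.67, miR-450a -0.87 to 0.49, miR-542-5p -0.39 to 0.40, miR-10a -0.55 to 0.21, miR-24-1* -1.10 to 0.37, miR-455* -0.32 to 1.28, miR-467c -0.50 to 0.42, miR-467d -0.78 to 0.55, miR-503* -0.63 to 0.39, miR-29a -0.063 to 0.43, miR-542-3p -0.021 to 0.45, miR-22 -0.11 to 0.66, miR-23b -0.65 to 0.00013 and miR-30a* -0.10 to 1.27. Mean log2 fold changes of lists whose camera direction turned ranged as follows: reported as lowered by ER stress -0.60 to 0.19, p53-linked -0.25 to 0.10, fibroblast and mesenchymal -0.26 to 0.056, miR-30 family -0.28 to 0.27, Dlk1-Dio3 cluster -0.35 to 0.24, hypoxia and metal stress -0.48 to 0.037, miR-29 family -0.33 to 0.066, let-7 family -0.65 to 0.058 and passenger-like mirtrons -0.60 to -0.11. The mean alone turned for neural markers, -0.60 to 0.57, and the miR-23, miR-27 and miR-24 clusters, -0.020 to 0.16. Differences in percentage points ranged from -0.0729 to 2.27 for mature reads, -0.494 to 0.224 for ambiguous reads, -1.30 to 0.0674 for star reads, -0.721 to 0.0242 for hairpin reads and -68.9 to 2.29 for longer reads. Of the values recomputed over alternatives, 1416 kept direction and side of the threshold, 95 turned, 7 passed the threshold only in the alternative, 4 only in the main analysis, and 8 counts of calls moved.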

Other observations

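The hypothesis on neighbouring genes was written before its test was run. If thapsigargin acted on whole miRNA clusters, hairpins within 10 kb of each other would have like fold changes. Over 75 hairpins in 29 clusters, each with its most abundant arm, cluster membership accounted for 35.4% of the variance of log2 fold changes, no more than in shuffled hairpins (permutation p = 0.6092, 10000 shuffles). The difference between the control replicates gave 44.5% (permutation p = 0.2006). A p that misses the threshold does not show that neighbours move apart. The miR-216a, miR-216b and miR-217 genes were not among these clusters, since miR-217 was too scarce to be tested and the others lie further apart.

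The control replicates differed in abundant miRNAs as well. miR-10b had 1375794 reads in control replicate 1 and 2057610 in control replicate 2, and 2324752 and 1432559 with thapsigargin. miR-183 had 3732 and 14731 reads in the controls and 3595 and 2601 with thapsigargin.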
